A study of Mus musculus with 5 samples.

How the data were processed

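Poly(A) RNA from whole pancreas was sequenced on an Illumina instrument after fragmentation and random priming, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2 and genome build mm8; the annotation, the gene quantification and any normalization are not given in the sources used here. The deposited files give 1 signal value per gene symbol and library, with the unit unstated, and hold the same 1457 genes in the same order plus 1 blank row each. No step of whole reads was found in the low values, with or without division by transcript length, so depth is unknown and no test for read counts was used, although such a test had been planned for the case of count files. The analysis plan was kept as written and its branch for normalized values was followed.

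The rows follow a falling ratio of the wild-type caerulein mean to the saline value with 0 rows out of order (tolerance 0.001 in log2). Each gene differs from saline by at least 2.528-fold in some caerulein library, and 1440 by at least 4-fold. Wild-type caerulein means exceed saline for 1412 genes, are lower for 44 and equal for 1. The table is thus a chosen part of the transcriptome, its sums are not library depths, and an adjusted p against saline describes genes that appear to have been chosen for that difference. The lowest value, 0.01, appears to stand for genes with no measured signal, and ubiquitous genes are among those at it, so fold changes against 0.01 are not given.

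Values were transformed to log2(value + 1) as deposited, without rescaling, and the log2 differences understate the change of low genes. Genes with a value of at least 1 in at least 2 libraries were tested (1429 of 1457). A limma 3.58.1 linear model in R 4.3.3 with 1 mean per group over all 5 libraries was fitted with a trended, robust empirical Bayes variance, and p-values were adjusted over genes by Benjamini-Hochberg at 0.05 within each of 3 comparisons. The residual degrees of freedom, 2 per gene, come from the caerulein groups, so the saline library is assumed to vary as they do. The knockout and wild-type comparisons with saline share that library, and their calls are therefore not independent.

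Of 31 gene lists, 5 had at least 4 measured members and were tested with camera (preset correlation 0.01, then an estimated correlation) and fry, adjusted over the 5 lists. Another 15 had 1 to 3 members, and 11, namely the microRNA lists and the mitochondrially encoded genes, had none. Of the symbols listed, the 1457 genes held 13 of 30 for matrix, 8 of 24 for macrophages and 8 of 24 for cell cycle. For interferon they held 4 of 19, and for miR-21 targets 5 of 44. List counts therefore cover only members that remained after the selection of genes. Genes named are the 12 largest rises and falls past the threshold whose groups do not overlap (6 for knockout against saline), the 10 smallest p-values where fewer than 10 passed, up to 4 members of each tested list, and the 10 highest genes in saline. Certain genes that this rule names are not reported here; they stayed in the tests and list counts. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Gene symbols were matched to current names or synonyms for 1454 of 1457 genes. Transcript length and GC content were available for 1451 genes (99.6%) from a newer mouse annotation than mm8, so no coordinates are given.

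The scripts were tested on simulated data in which 200 of 1429 genes were changed and libraries varied independently with an SD of 0.79, which leaves out the similarity between particular libraries seen in the data. For knockout against wild type, 55.3% of genes changed by 2 on the log2 scale were recovered, 82.1% at 3 and 100% at 4, with 3 calls among 1229 unchanged genes. For wild-type caerulein against saline the shares were 25% at 2, 66% at 3 and 93.1% at 4, with 5 such calls. All genes were given the same SD, below the median SE of 0.87 for knockout against wild type in the data. With 2 libraries against 2 that SE equals the estimated SD of a library. The 200 changed genes also ease the adjusted threshold. These shares therefore check the scripts and are not the power of the tests on the data. Alternatives were quantile normalization, equal sums without the 20 most abundant genes, no filter, a filter at 5, a pseudocount of 0.1, a variance estimate without robustness, only the 2 groups compared, and leaving out each caerulein library. Others were added after seeing the data: caerulein libraries scaled by their median ratio, only genes above 0.01 in all 5 libraries, and a block joining similar libraries. Correlation intervals used 2000 bootstrap draws of genes and list percentiles 10000 random lists matched on mean expression, in Python 3.11.15 with scipy 1.17.1.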

Results

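Messenger RNA was measured by sequencing in whole mouse pancreas. Caerulein, an analogue of the gut hormone cholecystokinin that induces acute pancreatitis when injected repeatedly, was given to wild-type mice (2 libraries, replicates 1 and 2) and to mice lacking the microRNA miR-21 (2 libraries, replicates 1 and 3). One wild-type library came from a saline-treated mouse, so that group has no replicate. The dose was 50 µg/kg and tissue was taken 24 h after the first injection, from female C57BL/6 mice aged 8 weeks. The labels do not say that each library is a separate mouse; if any were not, the p-values would measure technical spread.

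The table analysed here holds 1457 genes, and the unit of its values is not stated. The values of the listed genes summed to 2818 in the saline library, 38628 and 23255 in wild-type caerulein replicates 1 and 2, and 32770 and 34393 in knockout caerulein replicates 1 and 3. The read depth is unknown, so no counting interval could be given. In the saline library 540 genes (37.1%) were listed at the lowest value, 0.01, against 34, 89, 41 and 31 genes in the caerulein libraries in the order above. The highest values in saline belonged to Eef1a1, a translation elongation factor, Rpl41, Rplp1 and Rpl14, ribosomal protein genes, Ubb, a ubiquitin gene, and Ftl1, a ferritin chain. Wdr89, Hbb-b2, a haemoglobin chain, Zc3h11a and Eif5a completed the 10 highest. Neither miR-21, its primary transcript nor the neighbouring gene Vmp1 was among the 1457 genes, so the deletion was not checked here.

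The first comparison asked which transcripts differed in wild-type pancreas a day after the first caerulein injection. Of 1429 genes tested, 1274 stood higher in both caerulein libraries than in saline, in a set that appears to have been chosen for such differences. Past the threshold 819 of the 1429 rose, with 11 of 13 matrix genes and 5 of 8 macrophage genes among them. Col3a1, a fibrillar collagen, was 0.38 in saline and 525.1 and 50.15 in the caerulein libraries, a log2 difference of 6.89 (SE 1.17). Laptm5, a lysosomal membrane protein of blood cells, rose by 6.38 on the log2 scale (SE 1.18), from 1.24 to 167.2 and 207.34. Mpeg1, a pore-forming protein of macrophages, rose from 0.38 to 84.72 and 51.56 (log2 difference 5.60, SE 1.10). Sdc1, a heparan sulfate proteoglycan, rose from 0.43 to 85.79 and 36.72, and the histone variant gene H2afz from 0.40 to 35.39 and 79.46.

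Several of the genes with the largest rises were listed at 0.01 in saline, so no fold is given for them. Fn1, which encodes fibronectin, reached 75.92 and 21.04, and the collagen gene Col5a2 70.38 and 22.17. Lcp1, an actin-bundling protein of leukocytes, reached 43.97 and 28.81. Tuba1c, an alpha-tubulin, reached 57.3 and 41.02, Gnpda1 26.09 and 46.42, and Vdac3, a mitochondrial outer membrane channel, 41.91 and 26.58. BC048507 rose from 1.87 to 109.59 and 213.6. Tubulin, histone and ribosomal protein genes have near-identical copies between which short reads can be divided, so their values are uncertain.

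In the stellate cell and matrix list 11 of 13 measured members rose and 2 did not pass, also when adjusted over the list alone. Postn, a matrix protein of activated fibroblasts, rose from 0.33 to 78.38 and 18.54. The list's median log2 difference was 4.56, against 2.71 for all tested genes. Limma's camera gave it an adjusted p = 2.577e-06 with a preset correlation between genes, and an adjusted p = 0.8724 with an estimated correlation. In the monocyte and macrophage list 5 of 8 members rose (5 adjusted over the list alone); Ctss, a lysosomal protease, went from 0.59 to 54.18 and 25.45. Emr1 and Mrc1, macrophage surface receptors listed at 0.01 in saline, reached 57.43 and 9.27, and 41.08 and 2.94. In the cell cycle list 6 of 8 members rose (6 adjusted over the list alone), among them Tk1, thymidine kinase, from 0.46 to 22.15 and 21.62, Mki67, from 0.02 to 12.94 and 7.63, Birc5 and Mcm3. In the interferon list 3 of 4 rose (3 adjusted over the list alone), Ifit3 and Oas1a among them, while Gbp2 was 1.07 in saline and 8.91 and 5.98 after caerulein. Of 5 published miR-21 targets 2 rose (2 adjusted over the list alone), Tgfbi, a secreted matrix protein that is also in the matrix list, and Timp3, an inhibitor of metalloproteases. Camera's adjusted p was 0.174 for the macrophage list, 0.7334 for cell cycle, 0.7941 for interferon and 0.8644 for the miR-21 targets. Their median log2 differences were 3.36, 3.26, 2.77 and 2.53 in that order, against 2.71 for all tested genes. Since 819 of 1429 tested genes rose, the member counts of these lists do not set them apart.

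A further 15 lists had 1 to 3 measured members each, 26 genes in all, of which 13 rose and 13 did not pass. Over all tested genes 819 of 1429 rose. Krt8, a keratin of simple epithelia, rose from 7.78 to 352.53 and 142.86, Jun from 2.01 to 41.82 and 37.25, and Cckar, the cholecystokinin receptor, from 0.42 to 35.72 and 9.29. Of 38 acinar enzyme symbols listed, only 3 were among the analysed genes. The others may be missing because of how the genes were selected, so these 3 do not show how the class changed. Prss3 (384.9 and 6.97 in replicates 1 and 2) and Klk1 (562.8 and 22.23) rose, though unevenly. The third, Prss1, was 0.01 in every wild-type library and 6.5 and 12.28 in the knockout, and passed in no comparison. All 3 have close paralogs.

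**Figure D1:**
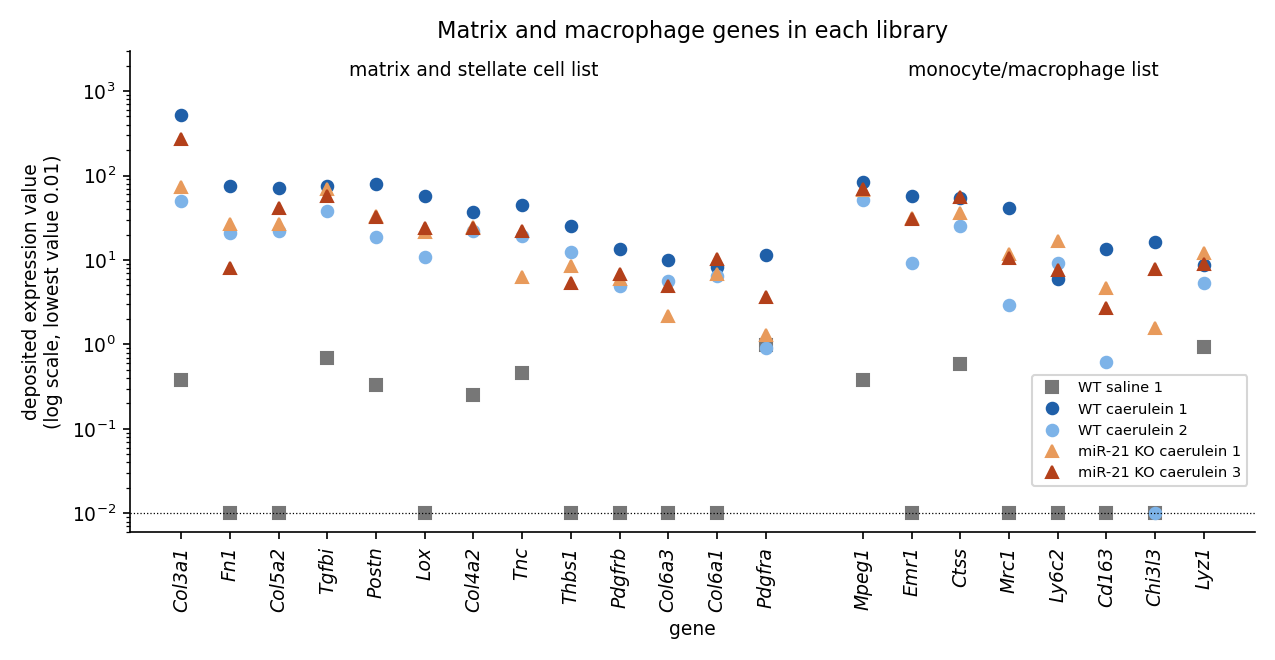
Deposited values (log axis, unit not stated) of the measured stellate cell and matrix genes and monocyte and macrophage genes, 1 point per library, with the lowest value 0.01 dotted. Saline (squares) lies lowest or at 0.01 for most genes, and replicate 1 of wild-type caerulein is often the highest, as for Col3a1 at 525.1.

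Over all tested genes limma called 819 of 1429 higher and 0 lower after caerulein (adjusted p under 0.05; 915 at an unadjusted p under 0.05), of which 325 were listed at 0.01 in saline. For 1289 genes (90.2%) the saline value lay outside the caerulein values, where chance gives 66.7% for unselected genes. The genes stand in exact order of their ratio to this 1 saline library, and all differ from it by at least 2.528-fold in some caerulein library. The p-values and this share therefore come from genes that appear to have been selected for the difference. The count fell to 210 higher and 40 lower with equal library sums and to 0 higher and 9 lower with quantile normalization, both of which force the saline library to match, and was 511, 377 and 509 without wild-type replicate 1, knockout replicate 1 and knockout replicate 3.

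The second comparison set knockout caerulein against the same saline library, to show the change from the baseline available, which is of another genotype as well as another treatment. Most tested genes again rose, 11 of 13 matrix genes and 6 of 8 macrophage genes among them. Col3a1 was 73.25 and 271.09 in knockout replicates 1 and 3 (log2 difference 6.69, SE 1.17), Laptm5 213.33 and 180.11 (6.46, SE 1.18) and Mpeg1 67.15 and 69.34 (5.65, SE 1.10). Prss3 rose from 1.90 to 150.18 and 289.84, BC048507 to 254.58 and 86.72, and Sdc1 to 71.34 and 69.07. Only Srsf2, a splicing factor, and Hbb-b2 fell, from 14.65 to 0.01 and 7.04 and from 25.6 to 1.37 and 8.90, and neither passed without knockout replicate 1.

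In the matrix list 11 of 13 members rose (11 adjusted over the list alone), with a median log2 difference of 3.97 against 2.80 for all tested genes; limma's camera gave an adjusted p = 0.002601, and adjusted p = 0.7629 with an estimated correlation. Col5a2, Tgfbi and Postn were among them. Of the macrophage list 6 of 8 rose (6 adjusted over the list alone; camera adjusted p = 0.08532), among them Emr1, Ctss and Mrc1. Of the cell cycle list 5 of 8 rose (5 adjusted over the list alone; camera adjusted p = 0.6336), including Tk1, Birc5, Mki67 and Pcna. In the interferon list 3 of 4 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.5757). Of the miR-21 targets 3 of 5 rose, Tgfbi and Timp3 among them (3 adjusted over the list alone; camera adjusted p = 0.4854). Pias3 was 4.01 in saline and 13.54 and 17.09 in the knockout.

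Limma called 861 of 1429 genes higher and 2 lower (966 at an unadjusted p under 0.05), 322 of the called being listed at 0.01 in saline. The count was 29 without knockout replicate 1 and 399 without knockout replicate 3, and changed to 206 higher and 29 lower with equal sums and to 0 higher and 6 lower with quantile normalization.

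The third comparison, knockout against wild type after caerulein, compared levels after treatment in mice with and without miR-21; with no knockout saline library, a changed response and a difference present before treatment cannot be separated. No gene passed the test. The smallest p belonged to Hnrnph1, a splicing regulator, at 75.7 and 107.84 in the knockout and 18.71 and 10.8 in the wild type (log2 difference 2.58, SE 0.90; limma adjusted p = 0.9997). Set, a histone chaperone, was 17.35 and 36.71 in the knockout and 5.62 and 4.86 in the wild type. Pias3, an inhibitor of STAT signalling and published miR-21 target, was 13.54 and 17.09 against 7.09 and 5.04 (log2 difference 1.21, SE 0.82; limma adjusted p = 0.9997).

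Others among the 10 smallest p-values had one wild-type library near the lowest value. Anxa10 was 16.03 and 23.61 in the knockout and 12.32 and 0.01 in the wild type, and Atp5f1, an ATP synthase subunit, 11.41 and 19.44 against 15.27 and 0.01. Rab3ip and Pdcd10 were at 0.80 and 0.01 in wild-type replicate 2. In the other direction, Srsf2 was 0.01 and 7.04 in the knockout and 32.33 and 4.37 in the wild type, and Xist, the RNA of the inactive X chromosome, 2.24 and 4.38 against 28.07 and 8.43. Xist was listed at 0.01 in the wild-type saline library, although the mice were female. Lta4h, which makes the chemoattractant leukotriene B4, was 6.62 and 5.28 in the knockout and 23.25 and 16.14 in the wild type.

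Of the 13 matrix genes 0 were called, over all genes or adjusted over the list alone, and 2 had a log2 difference above 0. The list's median was −0.25, against 0.10 for all tested genes, and camera gave an adjusted p = 0.0002791. That call was lost with adjusted p = 0.7427 with an estimated correlation, and when either of 2 libraries was left out. Camera's adjusted p was 0.557 without wild-type replicate 1 (list median 0.33, all genes 0.50) and 0.2572 without knockout replicate 1 (list median −0.23, all genes 0.01). Fn1 was 26.42 and 8.08 in the knockout and 75.92 and 21.04 in the wild type, Thbs1, a matrix glycoprotein, 8.51 and 5.34 against 25.41 and 12.55, and Tnc 6.31 and 22.06 against 44.76 and 19.25. Col6a3 was 2.20 and 4.92 against 10.07 and 5.59.

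Among the 5 measured miR-21 targets 0 were called (0 adjusted over the list alone) and 4 had positive differences, with a median of 0.22 and a mean of 0.61. Camera gave p = 0.02068 and an adjusted p = 0.0517, and an adjusted p = 0.7427 with an estimated correlation. The median was 1.42 without wild-type replicate 1 (all genes 0.50) and −0.27 without wild-type replicate 2 (all genes −0.33). Its size thus depended on single libraries, and its sign followed a shift of all genes. Relative to the other genes, camera's direction for the list was up with any caerulein library left out. Tgfbi was 69.88 and 56.99 against 76.09 and 38.24, and Timp3 31.51 and 17.05 against 31.99 and 20.06. The macrophage, cell cycle and interferon lists had medians of 0.22, −0.15 and 0.16, each with a camera adjusted p of 0.4904 and 0 members called (0 adjusted over the list alone). With a library left out these medians ranged from −0.59 to 1.17, −0.44 to 0.28 and −0.33 to 0.77, so each took both signs. Ly6c2, a monocyte surface protein, was 16.86 and 7.65 against 5.89 and 9.15, and Lyz1, a lysozyme, 11.93 and 8.97 against 8.81 and 5.37. Emr1 was 31.76 and 30.54 against 57.43 and 9.27, and Ctss 35.89 and 55.91 against 54.18 and 25.45. Birc5, Plk1, Mcm3 and Top2a, genes of cell division, had log2 differences of −0.36, 0.58, −0.34 and −0.42. Ifit3 was 16.89 and 13.75 against 8.52 and 5.35, while Oas1a and Gbp2 differed by −0.37 and 0.20.

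**Figure D2:**
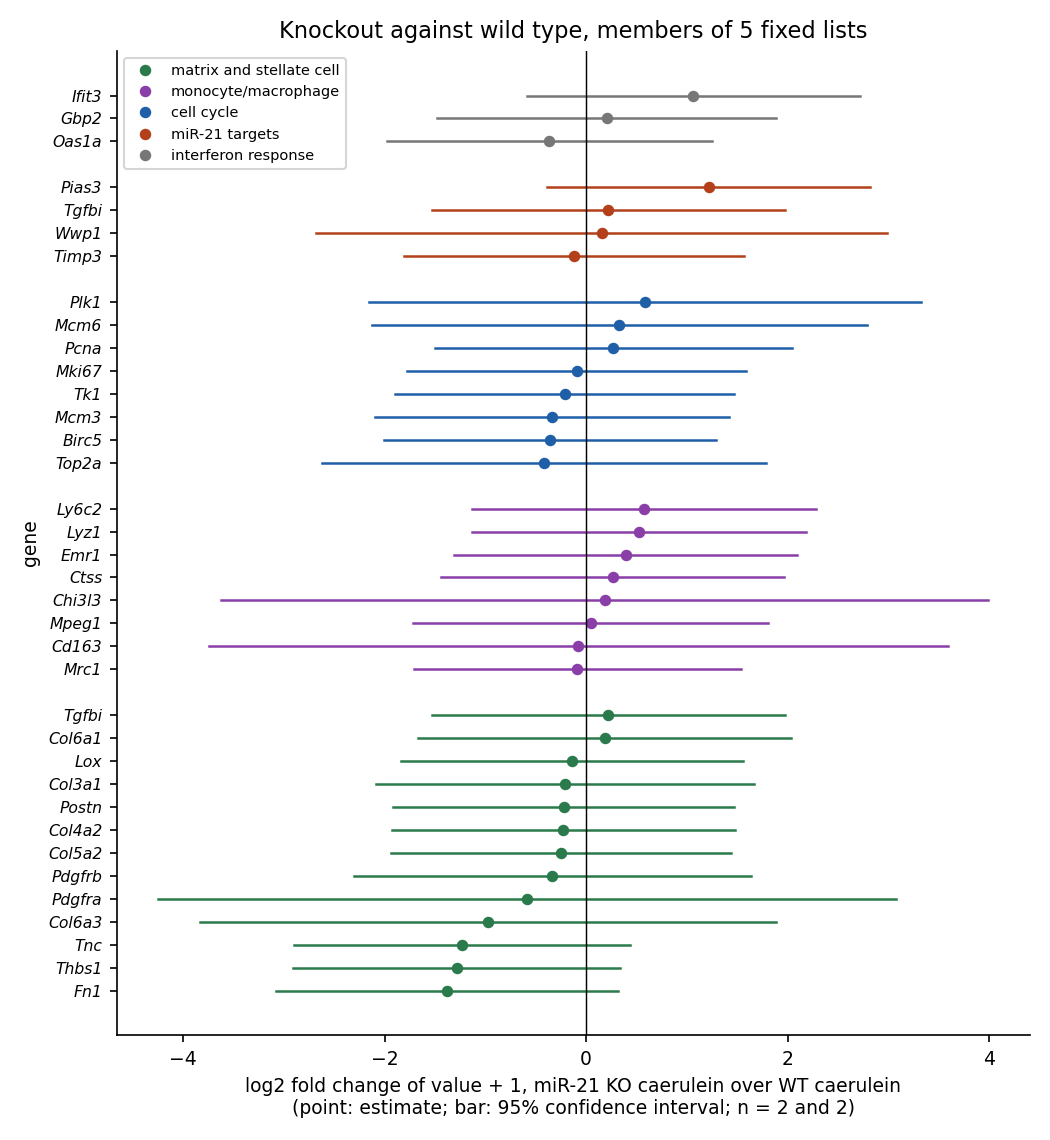
Log2 difference of value + 1 between knockout and wild-type caerulein libraries (2 and 2) for measured members of 5 lists, as the limma estimate (point) with its 95% confidence interval (bar). Fn1 lies lowest in the matrix list at −1.38 and Pias3 highest among the miR-21 targets drawn at 1.21, and both intervals include 0.

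Limma called 0 of 1429 genes (7 at an unadjusted p under 0.05, where 71 are expected by chance), and the groups did not overlap for 133 genes (9.3%), where chance gives 33.3%. The median 95% interval reached 1.71 on either side of the log2 difference, and for 571 genes (40.0%) it lay within a 4-fold change either way; these intervals leave out the similarity between particular libraries given next.

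The caerulein libraries differed more within a genotype than between certain libraries of different genotype. Across the 1429 genes, which are not independent replicates, Spearman's rho was 0.73 between wild-type replicate 1 and knockout replicate 3 and 0.74 between wild-type replicate 2 and knockout replicate 1. It was 0.35 between the wild-type libraries, 0.45 between the knockout libraries, 0.45 between wild-type and knockout replicate 1, and 0.42 between wild-type replicate 2 and knockout replicate 3. The labels give no batch for these libraries. With a block joining the similar libraries, a choice made after seeing the data, limma called 0 genes between the genotypes (16 at an unadjusted p under 0.05). Without wild-type replicate 1 limma called 4 genes higher in the knockout, Anxa10, Prss3, Hspd1 and Atp5f1, named after their values were seen, of which Anxa10, Hspd1 and Atp5f1 were at 0.01 in the remaining wild-type library.

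**Figure D3:**
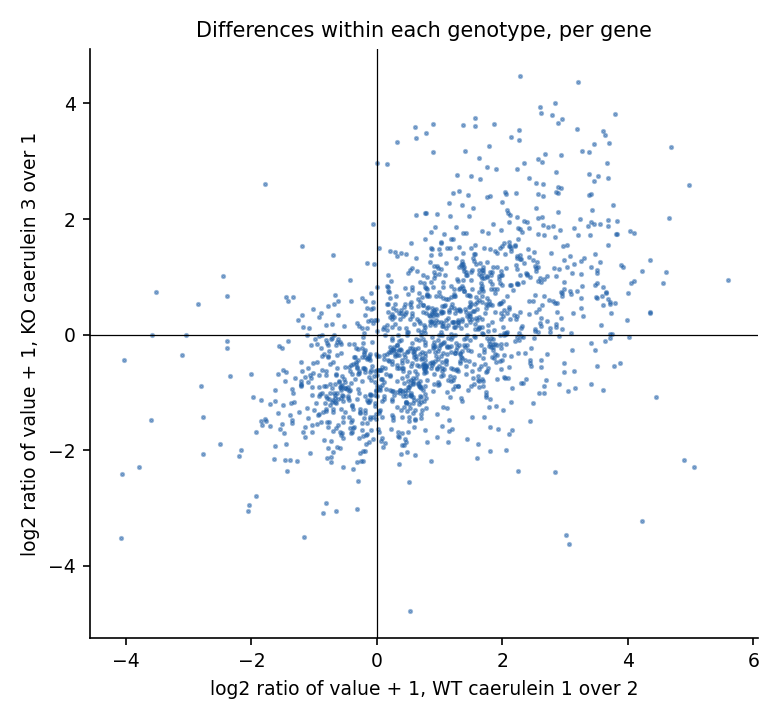
For each of 1429 genes, the log2 ratio of value + 1 between wild-type caerulein replicates 1 and 2 (horizontal axis) and between knockout caerulein replicates 3 and 1 (vertical axis). The 2 ratios rise together across genes, with a Pearson correlation of 0.52.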

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

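The median-ratio scaling, the restriction to genes above 0.01 and the crossed block were chosen after the data were seen. For knockout against wild type the count of genes was 0 under every setting run except without wild-type replicate 1 (range 0 to 4 over the libraries left out). The 819 genes called for wild-type caerulein against saline became 9 (all lower) with quantile normalization, 250 with equal sums, 440 with only the 2 groups compared and 488 with only genes above 0.01 in all 5 libraries (851 tested), and ranged from 377 to 1080 with a library left out. For knockout against saline, 863 became 6, 235 and 542 under quantile normalization, equal sums and the restriction to genes above 0.01, and ranged from 29 to 1028. Quantile normalization and equal sums took the median log2 difference from 2.71 to 0.07 and 0.79 (wild type) and from 2.80 to 0.08 and 0.82 (knockout), because they scale the saline library towards the others; a pseudocount of 0.1 took it to 3.88 and 4.15. Other settings gave counts within 1.5 times. Leaving out a library leaves 1 degree of freedom, with the lone library assumed to vary like the other group.

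The number of lists called, 1 in each comparison, was 0 with an estimated correlation and 0 with fry in all 3. For knockout against wild type it was 2 with median-ratio scaling, where the miR-21 targets joined at camera adjusted p = 0.03781 (range of camera over that list's other settings 0.0517 to 0.7427), and 0 to 1 with a library left out. It was 1 to 2 with a library left out for both saline comparisons, and for knockout against saline 2 with quantile normalization, 2 with equal sums and 2 with only the 2 groups compared. In both saline comparisons the list that joined the matrix list was that of macrophages. The interferon list's median for wild type against saline went from 2.77 to −0.01 under quantile normalization, as the median of all genes went from 2.71 to 0.07. Between genotypes the median of each of the 5 lists took both signs with a library left out, the matrix list from −1.30 to 0.33. The median of all genes ranged from −0.33 to 0.50 in those fits. Relative to the other genes, camera's direction there stayed down for the matrix list and up for the miR-21 targets. It changed for the macrophage, cell cycle and interferon lists.

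Against saline, directions turned under quantile normalization for Oas1a (−0.35) and Gbp2 (−0.86) in the wild type and Pias3 (−1.11), Oas1a (−0.61) and Gbp2 (−0.63) in the knockout, and under equal sums for Gbp2 (−0.48) in the wild type and Pias3 (−1.42), Oas1a (−0.37) and Gbp2 (−0.37) in the knockout. Between genotypes, the log2 difference with a library left out ranged from −1.32 to 0.48 for Top2a, −0.55 to 0.30 for Timp3, −0.031 to 3.98 for Atp5f1, −0.86 to 1.65 for Emr1, −0.27 to 0.79 for Ctss, −0.27 to 0.71 for Tgfbi, −0.39 to 0.80 for Gbp2, −0.0017 to 1.16 for Plk1 and −1.16 to 0.49 for Mcm3. Among the named genes' other values, 39 for wild type against saline and 40 for knockout against saline no longer passed, 5 in each newly passed, and 2 newly passed between genotypes.

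No paired analysis was possible because the caerulein groups share only replicate number 1. A crossed block called 0 genes. Alternatives that need read counts were not run, since the values are not counts. Unknown depth leaves the error of low values unmeasured.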

Other observations

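The gene families below were defined from symbol prefixes after the gene names had been seen, and those of collagens and Rab GTPases were narrowed after their values had been seen, to drop genes that share only the prefix; the tests of macrophage content and of exchanged labels were chosen after the result was seen; the other tests were set down before their own results but after the patterns had been noticed. Among 14 families compared between wild-type caerulein and saline, 8 of 11 collagen genes, some of them also in the matrix list, rose (median log2 difference 3.62), with a camera adjusted p = 0.02878, and adjusted p = 0.9857 with an estimated correlation. Of the mitochondrial ribosomal proteins 8 of 9 rose (median 3.22), and of the translation initiation factors 15 of 19 (median 3.17), with a camera adjusted p = 0.4295 for each. Adhesion and metalloprotease genes, which camera did not call either, rose in 5 of 6 cases (median 3.32). Over all tested genes 819 of 1429 rose (median 2.71). With equal library sums 7 collagen genes, 1 mitochondrial ribosomal gene and 3 initiation factors rose and 1 initiation factor fell, with medians of 2.94, 1.71 and 0.20 against 0.79 for all genes, and with quantile normalization 0 members of the 3 families were called by limma (medians 1.11, 0.69 and 0.49 against 0.07). Between genotypes limma called 0 members of any of the 14 families, and the smallest camera adjusted p was 0.4069. Xiap, an inhibitor of caspases, was 2.3 in saline, 5.6 and 5.01 in wild-type caerulein and 0.01 in both knockout libraries, and Pcsk2, a prohormone convertase of islets, was 15.59, 9.7 and 9.73, and 40.83 and 21.71; these were the 2 genes with both wild-type caerulein libraries on one side of saline and both knockout libraries on the other; neither was called, and the difference was not tested beyond limma's comparison of genotypes.

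Certain genes were seen in 1 library alone. The saline library had 21 genes at 5 or more that were at 1 or less in every other library (the highest at 16.92), Dok7 and Hydin among them, and wild-type caerulein replicate 2 had 8 (10.25 to 11.89), Gata3 and Erbb4 among them. The other 3 libraries had 0. Only 3 of the 1457 genes had a highest value under 9, so the table appears to have been selected on its highest value too, and the counts and narrow ranges above would depend on such a selection.

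The caerulein libraries resembled each other across labelled genotypes. The log2 ratios of wild-type replicate 1 to 2 and of knockout replicate 3 to 1 had a Pearson correlation of 0.52 across genes (95% bootstrap interval 0.47 to 0.56). This interval and those below resample genes, which are not independent, and do not measure the spread between mice or libraries. Wild-type replicate 1 with knockout replicate 3 set against the other libraries gave 190 genes (105 without the filter on low values), against 0 for the genotypes and 1, Cfd, for the remaining split, so the libraries have a structure other than the labelled genotype. The tables argue against length and GC content as the whole cause, since a correlation of 0.49 (0.44 to 0.54) was left after regression on them. Without regression the correlation was 0.62 (0.56 to 0.67) among genes whose mean caerulein value lay above the median. This argues against genes low in every caerulein library as the cause. A gene above that median can still be at 0.01 in 1 library, so values near 0.01 in single libraries were not excluded. Cytosolic ribosomal proteins (median ratios 1.55 and 1.33), splicing factors, initiation factors and respiratory chain genes lay above the middle 95% of random lists in both ratios, and U2af1, Eif2s2, Rian and Plagl1 were among the genes with the largest shared differences.

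Whether more macrophages in 2 of the libraries caused this pattern could not be decided. The macrophage list lay at percentile 92.44 in the wild-type ratio but 42.37 in the knockout ratio. Its median in the knockout ratio was −0.10 (SD over its 8 members 0.86), against 0.85 to 1.33 for the 4 families above. Those families were picked because they lay high in both ratios. In the knockout ratio the middle 95% of random lists matched to the macrophage list ran from −0.92 to 1.03. That range includes 0.85, so a list of 8 members is too small to exclude a rise of that size. In knockout replicates 1 and 3 Mpeg1 was 67.15 and 69.34, Emr1 31.76 and 30.54 and Mrc1 11.77 and 10.52. Ctss was 35.89 and 55.91 and Chi3l3 1.58 and 7.73, the direction that more macrophages would give. Ly6c2 was 16.86 and 7.65 and Lyz1 11.93 and 8.97, the opposite direction. An exchange of genotype labels cannot be told apart, because the 190 genes would follow from it and miR-21 is not among the genes analysed; the miR-21 targets, at percentiles 38.68 and 37.71, did not separate the libraries. An unlabelled processing batch or differences in severity between mice were not tested.

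Ubiquitous genes were listed at 0.01 in the saline library. Of 83 genes in 6 ubiquitous families (ribosomal, proteasome, initiation, respiratory and splicing), 23 (27.7%, Clopper-Pearson 95% interval 18.4 to 38.6) were at 0.01 in saline, against 0, 1, 1 and 0 in the caerulein libraries. Few reads outside the most abundant transcripts in the saline library would give this. Within the listed genes the 20 highest held 27.5% of the saline sum, against 28.4% to 34.7% in the caerulein libraries. These shares leave out every transcript outside the listed genes, which hold only 3 of 38 acinar enzyme symbols. They therefore cannot show whether such a concentration was present. Macrophage and matrix genes were at 0.01 more often, 12 of 21 (57.1%; Fisher's exact test, two-sided p = 0.018), as recruitment of such cells after caerulein would also give. The gene sets were not matched on expression. Few reads in saline could therefore also give such a difference, and the test cannot separate these explanations. Both predictions were met, but both tests ran on a table that appears to be chosen for low saline values, which raises such shares, so neither value measures how far each explanation accounts for the pattern.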
